A study of Mus musculus with 8 samples.

How the data were processed

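Nuclei were isolated from about 10 mm of cord around the injury site, cleaned with beads against nuclei, fixed and barcoded by split-pool combinatorial labelling (Parse Evercode WT v3), per the labels' protocols. All 12 animals were pooled into 8 sublibraries, which are the 8 deposited samples, and the deposited metadata give the animal of each nucleus. The replicate is therefore the animal, with 3 animals per condition and animal 3 labelled male in each. The genome build was mm39 and Seurat was used, with no version given, per the submitters' processing notes. The aligner, the counting tool and the gene annotation are not given in the sources used here.

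The deposited matrices hold raw UMI counts per gene and nucleus, not normalized, in 78298 gene rows. Rows without a gene symbol numbered 21883 and held 2.08% of the UMIs; they were tested like the others but not named. The authors filtered nuclei before depositing the filtered counts. That set holds 118240 of 168603 barcodes (70.1%), of which 49637 of the 50363 removed had under 500 UMIs. The deposited percent of mitochondrial UMIs reached at most 0.5 in the kept nuclei, and the deposited doublet score came with a class that was singlet in each kept nucleus; the tool that made the score is not given. Cell type names and the 39 cluster numbers were used as the authors deposited them. The names were checked with marker lists, which pointed to another class for clusters 30, 31, 33 and 37, and gave the class deposited as Div-Myeloid more OPC than myeloid marker RNA.

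Counts were summed per animal and cell type, for animals with at least 20 nuclei of the type. Each type was fitted in edgeR 4.0.16 with TMM factors, filterByExpr by condition and a robust quasi-likelihood fit, with all 4 conditions in one model and no covariate. In that fit 5 contrasts were tested, namely injury in wildtype, injury in knockout, knockout against wildtype in uninjured cord and at 7 dpi, and the interaction of injury and genotype. A gene was called at a Benjamini-Hochberg false discovery rate under 0.05 over the genes tested. Astrocytes and the microglia and macrophages carry the study's question and were taken as the main classes. Values are log2 fold changes with the standard error of the fit, or TMM-scaled CPM as mean and SD over the 3 animals of a condition; Plxnb1 per animal is given in CPM of the library total. The range of summed depth limits precision, since the 12 animals held 5875462 to 156342693 UMIs over all types. Intervals and floors cover counting error alone. Where all animals of a group had 0 UMIs the fold was computed against a floor of 3 UMIs over the group, and with 1 to 3 UMIs the ratio is given with a 95% exact Poisson interval.

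Shares of cell types were tested in edgeR on nuclei per type and animal, with the nuclei of the animal as library size and adjustment over the 10 types, beside two-sided exact permutation tests, which 3 animals against 3 cannot take below 0.1. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over state and pathway lists with at least 5 tested members, and over marker lists separately. Of the 54 lists, 10 describe cell states, 26 pathways, 17 cell type markers and 1 a technical response. The lists, the tests described so far and the rule for named genes were fixed before the data were examined. Tests and alternatives chosen later are named as such where they are given.

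The genes named were Plxnb1, then in the main classes the 10 highest and 10 lowest log2 changes among genes that passed with a mean log2 CPM of at least 5 and no overlap between the animals of the groups (the last not for the interaction), and 3 in each direction in the other types. The text gives the rule's genes in part, and up to 4 members with the smallest adjusted p of each list it speaks of, or 2 members with the highest level where none passed. Members of the plexin and semaphorin families may be named in any type. Predicted genes were skipped, and some genes that the rule takes are not reported here. In astrocytes 3 of the higher and 0 of the lower were skipped after injury in wildtype, 5 and 1 in knockout, 0 and 10 between uninjured genotypes, 0 and 0 at 7 dpi and 5 and 1 for the interaction. For microglia and macrophages these numbers were 1 and 5, 0 and 7, 0 and 7, 0 and 0, and 3 and 0.

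Animals of a condition were compared by a chi-square over genes. The 96 pairs gave a ratio to the degrees of freedom between 1.76 and 36.4, so no pair agreed within sampling noise. No block was used, as planned, and the replicate block and sex were run as alternatives. The correlation of same-numbered animals in astrocytes had a mean of 0.009, with single pairs from −0.476 to 0.331, and pairs reached 0.438 in neurons. The number does go with sex, since animal 3 is the male. The male label of animal 3 matched the sex-linked transcripts in each condition.

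The procedure was tested on counts simulated from the real gene means, dispersions and library sizes, with 200 genes changed. For astrocytes, genes changed by 1.5-fold, 2-fold and 4-fold were found in 7.46%, 25.4% and 81.8% for injury in wildtype (11875 genes), 16.4%, 43.3% and 97.0% in knockout (11870), 14.9%, 49.3% and 90.9% between uninjured genotypes (11875), 8.96%, 52.2% and 78.8% at 7 dpi (11881) and 2.99%, 16.4% and 54.5% for the interaction (11922). For microglia and macrophages the shares were 8.96%, 37.3% and 78.8% (9193 genes), 14.9%, 47.8% and 90.9% (9209), 7.46%, 32.8% and 74.2% (9200), 11.9%, 43.3% and 98.5% (9186) and 1.49%, 14.9% and 65.2% (9194) in the same order. In the share test a type raised 3-fold was called in 19 of 20 draws simulated for injury in wildtype; the other share contrasts were not simulated.

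Alternatives planned in advance numbered 18 and 7 were added later; among them were DESeq2 1.42.0, no TMM, no filter, other sets of nuclei, and leaving out each animal, and their effect is given at the end. The work ran in R 4.3.3 with the package data.table (1.17.8) and Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The gene order around Plxnb1 was taken from RefSeq genes of GRCm38.p6; no coordinates are given, since the counts are on mm39. The unfiltered counts were used only for the number of nuclei removed. Pericytes and the dividing class had too few nuclei in some animals for every contrast and are reported only where at least 2 animals per group remained.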

Results

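The data are RNA counts from single nuclei of mouse spinal cord. Wildtype mice and mice lacking Plexin-B1, a semaphorin receptor encoded by Plxnb1, were either uninjured or taken 7 days after a spinal cord injury (7 dpi), with 3 animals in each of the 4 conditions. The series asks how the loss of Plexin-B1 alters astrocyte activation and the interplay of glia after the injury. The authors kept 118240 nuclei with 587488322 unique molecules (UMIs) in all and named 10 cell types. Uninjured wildtype animals 1, 2 and 3 gave 8231, 12256 and 6043 nuclei and 26216986, 59130822 and 16162394 UMIs. Wildtype 7 dpi animals gave 7717, 9316 and 3164 nuclei and 17089174, 21168476 and 5875462 UMIs. Uninjured knockout animals gave 13324, 20685 and 15094 nuclei and 114875311, 156342693 and 120107096 UMIs. Knockout 7 dpi animals gave 4943, 8859 and 8608 nuclei and 12867917, 20670092 and 16981899 UMIs. The uninjured knockout animals stood apart in depth, with a median of 2089 to 2249 UMIs per nucleus against 947.5 to 1378 in the other 9 animals.

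Neurons made up 52.4% of the nuclei, oligodendrocytes 19.5%, astrocytes 10.4% (12301 nuclei), fibroblasts 5.38%, the class deposited as IAMs 4.99% (5903 nuclei), oligodendrocyte precursor cells (OPCs) 4.15%, ependymal cells 1.24%, endothelial cells (deposited as EC) 0.940%, a class of dividing cells (deposited as Div-Myeloid) 0.783% and pericytes 0.232%. The IAMs are called microglia and macrophages here, because their clusters were led by genes of these cells. Their cluster 16, led by Siglech, Cx3cr1 and Csf1r, held 90.1% of the class in uninjured wildtype and 87.2% in uninjured knockout cord, against 26.5% and 25.3% at 7 dpi. Their cluster 13, led by Gpnmb, Ms4a7 and F13a1, held 71.4% and 72.2% at 7 dpi. Astrocytes moved between clusters in the same way. Cluster 4 held 69.2% of wildtype and 70.7% of knockout astrocytes in uninjured cord, and cluster 5, led by C3, A2m, Gfap and Tnc, held 59.2% and 63.0% at 7 dpi. A small astrocyte cluster, number 37 with 192 nuclei, was led by the myeloid genes Csf1r, Csf3r and Ly86. Clusters 30 and 31 among the neurons and 33 among the fibroblasts were also led by markers of another class. The dividing class is mixed by its markers, with a median of 345 CPM for OPC markers against 40.2 CPM for microglia and 30.9 CPM for macrophage markers, so its changes are not read as those of myeloid cells. Its cluster 28, led by Top2a and Mki67, held 807 nuclei of this class, 59 OPCs and 17 ependymal cells.

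Plxnb1 (ENSMUSG00000053646) was lower in the knockout in uninjured astrocytes, oligodendrocytes, OPCs, fibroblasts and neurons, and at 7 dpi its difference passed the test in astrocytes alone. In wildtype astrocytes it stood at 261 ± 22.6 CPM (UMI counts scaled to a total of 1e6; SD, n = 3 animals) without injury and 275 ± 45.3 CPM at 7 dpi, and in knockout astrocytes at 90.4 ± 16.3 and 112 ± 15.1 CPM. The 6 wildtype animals lay between 225 and 315 CPM and the 6 knockout animals between 79.5 and 125 CPM. The fitted difference in astrocytes was −1.63 ± 0.16 on the log2 scale (estimate ± standard error) in uninjured cord (adjusted p = 6.6e-06) and −1.30 ± 0.17 at 7 dpi (adjusted p = 0.0026). Uninjured oligodendrocytes (−1.37 ± 0.16), OPCs (−1.58 ± 0.23), fibroblasts (−1.93 ± 0.31) and neurons (−1.24 ± 0.31) also had less Plxnb1 in the knockout, with adjusted p of 6.4e-07, 5.4e-05, 0.0030 and 0.0085 and no overlap between animals. In ependymal cells the difference did not pass (−1.20 ± 0.31, adjusted p = 0.16 uninjured; −0.29 ± 0.39 at 7 dpi). In microglia and macrophages Plxnb1 was sparse, with 31.1 ± 13.4 CPM in uninjured wildtype and 6.76 ± 2.45 CPM in uninjured knockout from 15 UMIs in each group, and its change missed the threshold (−2.13 ± 0.67, adjusted p = 0.092). Injury itself left Plxnb1 in wildtype astrocytes at a change of −0.05 ± 0.16 (adjusted p = 0.89). The remaining Plxnb1 counts in the knockout can come from parts of the gene outside the deletion, which the labels do not place, so they say nothing about residual protein.

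**Figure D1:**
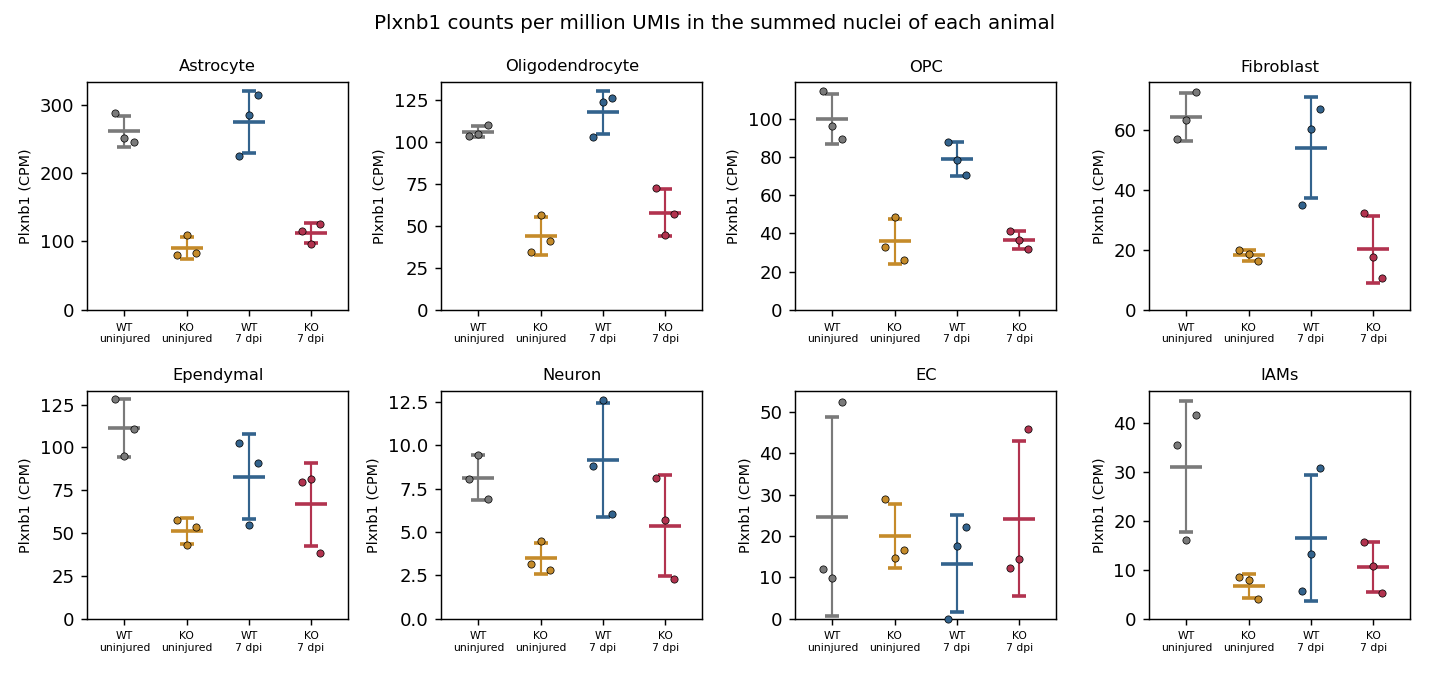
Plxnb1 level (CPM, vertical axis) in the summed nuclei of each animal, by cell type and condition; points are animals, bars the mean and whiskers 1 SD (n = 3). In astrocytes the 6 knockout animals lie at 79.5 to 125 CPM and the 6 wildtype animals at 225 to 315 CPM.

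Whether the injury or the genotype changed the make-up of the cord was asked from each cell type's share of an animal's nuclei. After injury microglia and macrophages rose from 1.80 ± 0.18% to 10.3 ± 1.41% of nuclei in wildtype and from 1.87 ± 0.26% to 10.2 ± 1.48% in knockout cord (SD, n = 3), and dividing cells rose from 0.168 ± 0.027% to 1.57 ± 0.093% and from 0.230 ± 0.143% to 1.86 ± 0.526%. Fibroblasts rose from 3.46 ± 0.64% to 8.6 ± 0.37% in wildtype and from 3.82 ± 1.09% to 7.46 ± 2.04% in knockout. OPCs rose from 2.46 ± 0.42% to 5.54 ± 0.38% and from 3.33 ± 0.03% to 6.72 ± 1.55%. Astrocytes rose from 7.91 ± 1.79% to 11.8 ± 0.26% and from 10.0 ± 1.30% to 13.9 ± 0.34%, while neurons fell from 60.3 ± 6.48% to 42.3 ± 4.56% and from 56.8 ± 1.07% to 43.2 ± 4.34%.

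The share test in edgeR called 7 of the 10 types in each genotype after injury, and with 1 animal left out 6 to 8 in wildtype and 4 to 7 in knockout. It called 4 in wildtype in nuclei of 500 to 2000 UMIs and 4 in knockout with neurons taken out of the total. In wildtype the log2 changes were 2.53 ± 0.19 for microglia and macrophages (5.76-fold, adjusted p = 7.7e-08), 3.26 ± 0.43 for dividing cells, 1.32 ± 0.25 for fibroblasts, 1.18 ± 0.20 for OPCs, 0.58 ± 0.18 for astrocytes (adjusted p = 0.013) and −0.51 ± 0.16 for neurons (adjusted p = 0.012), each with no overlap between the 3 injured and 3 uninjured animals. Endothelial cells were also called (0.66 ± 0.26, adjusted p = 0.039), with overlapping animals. In the knockout the changes were 2.44 ± 0.19 for microglia and macrophages (5.42-fold), 2.97 ± 0.38 for dividing cells, 1.01 ± 0.19 for OPCs, 0.97 ± 0.24 for fibroblasts, 0.47 ± 0.18 for astrocytes (adjusted p = 0.035), −0.58 ± 0.20 for oligodendrocytes (adjusted p = 0.021) and −0.40 ± 0.16 for neurons (adjusted p = 0.035), again without overlap. With neurons taken out of the total, the astrocyte share changed by 0.05 in wildtype (adjusted p = 0.76) and 0.08 in knockout, whereas microglia and macrophages still rose by 1.97 and 2.04 and oligodendrocytes fell by 0.91 and 0.98 on the log2 scale. Two-sided exact permutation tests of 3 animals against 3 cannot go below p = 0.1, which every type without overlap reached.

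With all nuclei no share passed the test between genotypes, but in nuclei of at least 1000 UMIs 2 types did in uninjured cord and 2 for the interaction. Between knockout and wildtype the smallest adjusted p was 0.40 in uninjured cord (OPCs, 0.44 ± 0.19, 3 of 3 knockout animals above the wildtype animals) and 0.63 at 7 dpi (astrocytes, 0.23 ± 0.18, also 3 of 3). For the difference between the 2 injury responses it was 0.74 (endothelial cells, −0.71 ± 0.37). edgeR counted 0 types below 0.05 in these 3 contrasts, and 1 type had an unadjusted p below 0.05 in uninjured cord.

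**Figure D2:**
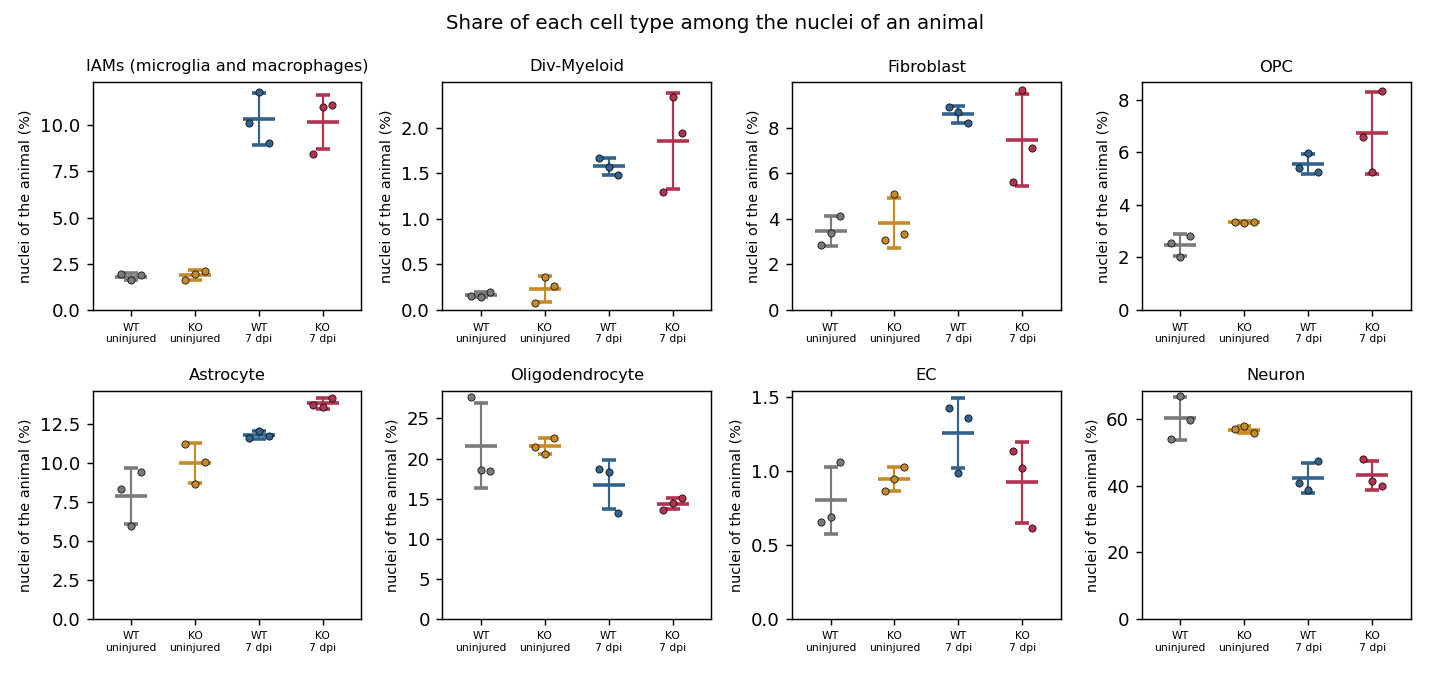
Share of each cell type among the nuclei of an animal (percent, vertical axis) by condition; points are animals, bars the mean and whiskers 1 SD (n = 3). Microglia and macrophages (IAMs) rose from 1.80% to 10.3% of nuclei in wildtype and from 1.87% to 10.2% in knockout cord.

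What the injury did to astrocytes that have Plexin-B1 was asked by comparing wildtype astrocytes at 7 dpi with uninjured wildtype astrocytes. Genes of the reactive state rose. Gfap, the astrocyte intermediate filament, went from 852 ± 310 to 4051 ± 396 CPM (4.77-fold; SD, n = 3), Osmr, the oncostatin M receptor, from 12 ± 6.83 to 157 ± 31.8 CPM (11.6-fold), and Nes, the filament protein of neural progenitors, from 5.62 ± 2.97 to 76.9 ± 36.3 CPM (13-fold). Among the genes that fell, Glul, which makes glutamine from glutamate, went from 317 ± 35.2 to 46.4 ± 16.2 CPM (7.31-fold lower) and Grin2c, an NMDA receptor subunit, from 166 ± 14.8 to 25 ± 3.33 CPM. For every gene named for this comparison the 3 injured and 3 uninjured animals did not overlap, unless stated.

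The list of pan-reactive astrocyte genes rose in 9 of its 10 tested members with a median log2 change of 2.52, among them Osmr (3.53 ± 0.29), Vim (2.78 ± 0.33), Gfap (2.26 ± 0.21) and the hyaluronan receptor Cd44 (1.98 ± 0.20). All 6 tested genes of the A2 list rose, with a median of 2.03, among them Cd109 (2.09 ± 0.25) and Clcf1 (1.78 ± 0.35). Tgm1 of that list went from 1 to 156 UMIs, a ratio of 136 with a 95% counting interval of 24.1 to 5420. Of the 7 tested A1 genes C3 (2.15 ± 0.23), Serping1 (2.36 ± 0.37) and Ggta1 (1.94 ± 0.30) rose and Fkbp5 fell by 2.24. Intermediate filament genes rose in 6 of 7 (median 1.45), including Dst (0.92 ± 0.14) and Lmna (1.45 ± 0.23). Genes of fibrotic matrix rose in 9 of 20 and fell in 1 (median 1.02), with Col12a1 at 2.41 ± 0.19, Col5a3 at 2.32 ± 0.28 and Col5a2 at 1.66 ± 0.21. The list named for disease-associated microglia rose in 8 of 12 (median 1.04), with Gpnmb (3.83 ± 0.46) and the tetraspanins Cd9 (1.78 ± 0.24) and Cd63 (1.10 ± 0.20). Camera called the pan-reactive (adjusted p = 1.3e-16), A2 (9.9e-07), filament (5.3e-10), fibrotic matrix (8.3e-07) and microglial (5.2e-06) lists, and these 5 of its 19 calls held with an estimated correlation. The marker genes of macrophages were higher in these astrocyte nuclei, with 2 of 4 called (3 adjusted over the list alone) and a median of 2.49. Gpnmb stood at 2005 CPM in wildtype microglia and macrophages at 7 dpi. The rise of the microglial list therefore cannot be assigned to astrocytes alone, and RNA from myeloid cells was not tested as its source. Those of oligodendrocytes had a median of −2.30 with 1 of 10 lower, and Mbp (−2.40 ± 0.96), which did not pass, had overlapping animals.

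Actin and migration genes rose in 14 of 33 (16 adjusted over the list alone, median 0.53), among them Actn1 (2.52 ± 0.22), Msn (1.85 ± 0.23) and Flna (1.63 ± 0.22), with a camera adjusted p of 1.3e-06, and adjusted p = 0.052 with an estimated correlation. Homeostatic astrocyte genes fell in 12 of 22 and rose in 1 (14 and 1 adjusted over the list alone, median −0.70). They included Glul (−2.87 ± 0.20), the glypican Gpc5 (−1.80 ± 0.15), the gap junction gene Gjb6 (−1.54 ± 0.17) and the amino acid transporter Slc7a10 (−1.29 ± 0.16), with adjusted p = 0.085 for the list with an estimated correlation. Within cluster 5 alone the direction turned for Gpc5 in astrocytes (1.00) and Slc7a10 in astrocytes (1.06). Cholesterol synthesis genes fell in 8 of 19 (14 adjusted over the list alone, median −1.0), with Nsdhl at −2.13 ± 0.24 and Lss at −1.59 ± 0.39, and adjusted p = 0.26 with an estimated correlation. Of the list around STAT3 and gp130, the shared receptor of interleukin 6 cytokines, 6 of 13 rose, including Bcl3 (3.00 ± 0.29) and Stat3 (1.06 ± 0.15), and 2 fell, including Lifr (−1.05 ± 0.15), with adjusted p = 0.08 by the estimated correlation. Of the plexins and neuropilins Plxnb2 (1.14 ± 0.24), Plxnd1 (2.28 ± 0.34) and Nrp2 (1.10 ± 0.15) rose, 3 of 11. Of 16 semaphorins Sema3a (1.33 ± 0.21), Sema6a (0.74 ± 0.17) and Sema6d (0.58 ± 0.14) rose and Sema4b fell by 0.61, and neither list was called. The direction turned within cluster 5 alone for Sema6d in astrocytes (−0.0854) and Sema4b in astrocytes (0.435), and within cluster 4 alone for Sema6a in astrocytes (−0.0678). Of 17 genes of Plexin-B signalling Met (1.46 ± 0.22) and Rnd3 (1.49 ± 0.29) rose and 2 fell.

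In all 2241 of 12456 tested genes changed, 1264 higher and 977 lower (edgeR, false discovery rate 0.05), and 2130 of these had groups without overlap. Over all tested genes 32.2% had no overlap, where chance gives 10%. Other high changes were those of Anxa3 (3.56 ± 0.38), Nox4 (3.50 ± 0.33), Dysf (3.49 ± 0.27), Iqgap2 (3.48 ± 0.27) and the filamin Flnc (2.98 ± 0.19), and other low ones those of Etnppl (−2.93 ± 0.46), the transcription factor Zbtb16 (−2.81 ± 0.27), Tsc22d3 (−2.74 ± 0.20), Cables1 (−2.65 ± 0.17) and the phagocytic receptor Mertk (−2.40 ± 0.23). Within cluster 4 alone 908 genes changed and within cluster 5 alone 790, and without the clusters led by markers of another class (30, 31, 33 and 37) the count was 2291. Without TMM factors the split was 1638 higher and 692 lower, and the median change of all genes in the Astrocyte class was 0.11.

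Whether astrocytes without Plexin-B1 respond to injury was asked with the same comparison in the knockout. The reactive genes rose here too. Gfap went from 662 ± 55.9 to 3411 ± 527 CPM (5.15-fold), Osmr from 15.3 ± 3.79 to 160 ± 26.3 CPM (10.4-fold), Vim from 12.9 ± 3.14 to 102 ± 25.9 CPM (7.77-fold) and Nes from 2.99 ± 0.565 to 77.7 ± 35.1 CPM (25.4-fold; SD, n = 3, no overlap). All 10 pan-reactive genes rose (median 2.80, camera adjusted p = 4.5e-11), as did all 7 filament genes (median 1.88, 1.8e-09), and both calls held with an estimated correlation, the only 2 of 15 that did. Cholesterol synthesis genes fell in 19 of 19 (median −2.47), with Hmgcs1, the entry enzyme of the pathway, at −3.09 ± 0.35, Idi1 at −3.39 ± 0.33, Cyp51 at −2.63 ± 0.22 and Sqle at −2.62 ± 0.24. The camera adjusted p was 2.8e-21, and adjusted p = 0.098 with an estimated correlation. Hmgcs1 stood at 228 CPM in uninjured knockout against 41.9 CPM in uninjured wildtype, and at 26.7 against 19.8 CPM at 7 dpi. The fall in the knockout therefore also holds a difference present before injury.

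Homeostatic genes fell in 18 of 22 and rose in 2 (median −1.07), with Gja1, which encodes connexin 43, at −2.29 ± 0.19, Gpc5 at −2.01 ± 0.15, Gjb6 at −1.88 ± 0.16 and Slc7a10 at −1.47 ± 0.16, and adjusted p = 0.092 with an estimated correlation. Within cluster 5 alone Gpc5 in astrocytes was at 0.81 and Slc7a10 in astrocytes at 1.09. Actin and migration genes rose in 20 of 33 and fell in 2 (median 0.85), among them Actn1 (2.86 ± 0.19), Flna (2.05 ± 0.20) and Msn (1.75 ± 0.19), with adjusted p = 0.088 by the estimated correlation. Of the plexins Plxnd1 (2.20 ± 0.25), Plxna3 (1.44 ± 0.23), Plxnb2 (1.13 ± 0.20) and Plxna1 (0.88 ± 0.19) were among 5 of 11 that rose (camera adjusted p = 0.021, and adjusted p = 0.14 with an estimated correlation). Of the semaphorins Sema3a rose (0.93 ± 0.18) and Sema4b fell by 0.45, and within cluster 5 alone both turned, Sema3a in astrocytes to −0.289 and Sema4b in astrocytes to 0.525. The macrophage markers were higher in all 4 tested genes (median 2.08). In all 5476 genes changed, 2953 higher and 2523 lower, of which 5244 had groups without overlap, against 55.3% of all genes and 10% by chance. Uninjured knockout astrocytes held a mean of 3195 UMIs per nucleus against 1637 in uninjured wildtype. The counts of the 2 genotypes therefore do not rest on equal depth. Gja1 and Gpr37l1, which fell here, were higher in uninjured knockout than in uninjured wildtype. Other high changes were those of Anxa3 (4.16 ± 0.30), Iqgap2 (3.74 ± 0.22), Dysf (3.73 ± 0.22), the receptor tyrosine kinase Ephb2 (3.14 ± 0.21) and the integrin Itga5 (2.94 ± 0.24), and other low ones those of Gpr37l1 (−3.38 ± 0.22), Lgr6 (−3.38 ± 0.24), Selenop (−3.22 ± 0.22), Tril (−3.12 ± 0.22) and the transporter Slco1c1 (−2.98 ± 0.19; 0.154 for Slco1c1 in astrocytes of cluster 5 alone). Within cluster 4 alone 2617 genes changed and within cluster 5 alone 3627, and in nuclei of 500 to 2000 UMIs 3446 did.

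The 2 injury responses shared direction. Of the 2241 genes called in wildtype astrocytes 93.2% moved the same way in knockout astrocytes, whose animals are separate, and 990 were higher in both (300 by chance) and 679 lower in both (198 by chance), while 25 were called in opposite directions. Across 5423 abundant genes, which are not independent replicates, the log2 changes correlated with r = 0.697.

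**Figure D3:**
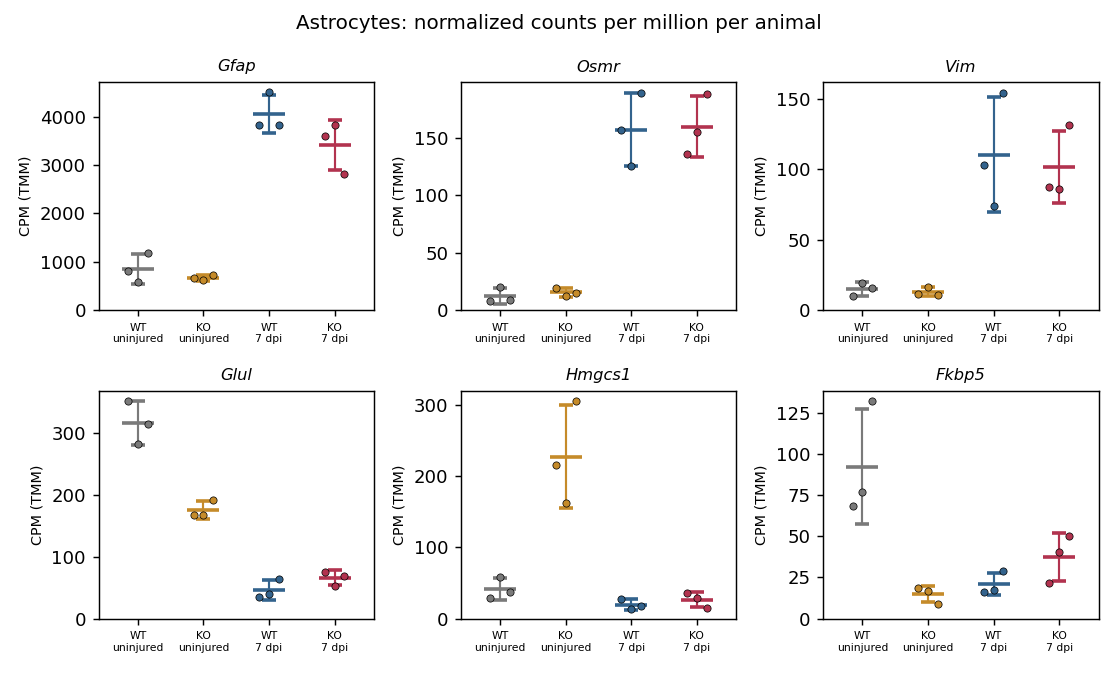
Levels of 6 astrocyte genes (CPM, vertical axis) by condition; points are animals, bars the mean and whiskers 1 SD (n = 3). Gfap rose from 852 to 4051 CPM in wildtype and from 662 to 3411 CPM in knockout, and Hmgcs1 stood at 228 CPM in uninjured knockout against 41.9 CPM in uninjured wildtype.

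What the loss of Plexin-B1 does to astrocytes in the intact cord was asked by comparing uninjured knockout with uninjured wildtype. The genes of cholesterol synthesis were higher in the knockout. Hmgcs1 stood at 228 ± 72.2 against 41.9 ± 15.3 CPM (5.23-fold; SD, n = 3) and Cyp51 at 206 ± 53.7 against 48.6 ± 11.3 CPM (4.17-fold). Among the lower genes were Fkbp5, a target of the glucocorticoid receptor, at 14.8 ± 4.95 against 92.4 ± 34.7 CPM (6.07-fold lower), and Zbtb16 at 203 ± 60.1 against 1121 ± 148 CPM (5.48-fold lower). Animals of the 2 groups did not overlap for any gene named here.

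Of the 19 cholesterol genes 18 rose and none fell (19 adjusted over the list alone, median 1.73), including Idi1 (2.66 ± 0.34), Cyp51 (2.06 ± 0.22), Sqle (1.87 ± 0.24) and Dhcr7 (1.77 ± 0.25); camera gave an adjusted p of 1e-27, and adjusted p = 0.19 with an estimated correlation. Homeostatic genes went both ways, 4 of 22 higher and 3 lower, with the water channel gene Aqp4 at 1.82 ± 0.18 and Gja1 at 1.56 ± 0.19 but Fgfr3 at −0.90 ± 0.15 and Glul at −0.84 ± 0.16, and the list was not called. Of the pan-reactive genes Cd44 was higher (0.98 ± 0.19) and Aspg lower (−1.21 ± 0.27). Cell adhesion genes were higher in 5 of 25, including Cdh11 (0.72 ± 0.15) and Tjp1 (0.62 ± 0.14), and of the list of disease-associated microglia the lysosomal proteases Ctsb (1.51 ± 0.19) and Ctsl (1.38 ± 0.26) were higher. With an estimated correlation adjusted p = 0.62 for adhesion and adjusted p = 0.25 for the microglial list, and none of the 6 camera calls held. The guidance receptor gene Nrp1 (0.54 ± 0.16) and Sema6a (0.54 ± 0.16) were higher and Sema5b lower (−1.64 ± 0.46), and of 17 Plexin-B signalling genes 5 were higher. Neuron markers were lower in 3 of 5, namely Meg3 (−1.21 ± 0.28), Rbfox3 (−1.24 ± 0.34) and Snap25 (−0.74 ± 0.23), with adjusted p = 0.88 with an estimated correlation. In nuclei of 500 to 2000 UMIs Snap25 in astrocytes was at 0.12.

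In all 1802 genes differed, 877 higher and 925 lower, of which 1764 had no overlap, against 37.2% of all genes and 10% by chance. Other high changes were those of Hsd17b7, also of cholesterol synthesis (2.85 ± 0.28), Serinc1 (2.21 ± 0.24), Gpr37l1 (2.15 ± 0.21), Tmem47 (2.08 ± 0.19) and Col12a1 (1.86 ± 0.18), and other low ones those of Erdr1y (−3.17 ± 0.48), the ribosomal RNA gene Rn18s-rs5 (−2.01 ± 0.18), Slc24a4 (−1.93 ± 0.19) and Hif3a (−1.88 ± 0.28). The median UMIs per astrocyte nucleus were 1409 in the knockout and 1374.5 in wildtype, but the means were 3195 and 1637. Without wildtype animal 3 the count was 936, and without knockout animals 1, 2 and 3 it was 975, 1062 and 978. Without TMM factors the Astrocyte split was 1315 higher and 645 lower, without the filter on low counts it was 1647 and 578, within cluster 5 alone 583 genes differed and within cluster 4 alone 1165.

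At 7 dpi, where the loss of Plexin-B1 in reactive astrocytes is the question, knockout and wildtype astrocytes differed in 3 of 12456 genes, all lower in the knockout and without overlap. Besides Plxnb1 (111 ± 16.3 against 276 ± 49.9 CPM with TMM factors, 2.46-fold lower) they were Slc38a3, a glutamine transporter, at 108 ± 14.2 against 218 ± 21.7 CPM (−1.03 ± 0.14, adjusted p = 0.0042) and Dao, D-amino acid oxidase, at 39.8 ± 5.83 against 89.1 ± 19.5 CPM (−1.20 ± 0.19, adjusted p = 0.014). Slc38a3 lies 37 genes from Plxnb1 in the gene order of GRCm38.p6. The reactive genes Gfap (−0.25 ± 0.20) and Cd44 (−0.08 ± 0.17) did not pass the test. No list member other than Plxnb1 was called. Camera called homeostatic genes lower (median −0.21, with Gpc5 at −0.17 ± 0.15 and Slc1a2 at −0.24 ± 0.16), cholesterol genes higher (median 0.38) and myelin genes higher (median 1.38, with Mbp at 1.59 ± 0.94). Each had adjusted p = 0.96 with an estimated correlation. The oligodendrocyte markers had a median of 1.43 in these astrocyte nuclei and those of OPCs 0.44.

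Unadjusted p was below 0.05 for 460 genes, and 8.15% of genes had no overlap where chance gives 10%. DESeq2 also called 3 genes. In simulated data of this size 52.2% of genes changed by 2-fold and 8.96% of those changed by 1.5-fold were found. The count was 2 without wildtype 7 dpi animal 1, 1 without animal 2 and 0 without knockout 7 dpi animal 2, 1 within cluster 4 alone, and 15 without the filter on low counts.

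Whether the injury response itself depends on Plexin-B1 was asked with the interaction of injury and genotype, which 369 astrocyte genes passed, 185 with a higher and 184 with a lower change in the knockout. The interaction is the genotype difference at 7 dpi minus that in uninjured cord, so a difference in uninjured cord alone can pass. Between the genotypes 1802 genes differed in uninjured cord and 3 at 7 dpi. Hsd17b7, Tmem47, Gpr37l1, Col12a1 and Aqp4 were higher in uninjured knockout and had a negative interaction. Fkbp5, Zbtb16, Erdr1y and Rn18s-rs5 were lower there and had a positive one. The count thus does not place a difference in the injury response itself. Plxnb1 did not pass (0.33 ± 0.23, adjusted p = 0.45). The genes with a more negative response in the knockout included those of cholesterol synthesis, 5 of 19 (11 adjusted over the list alone, median −1.24). Cyp51 changed by −2.63 in knockout and −0.74 in wildtype after injury, and Hsd17b7 by −2.14 and 0.52. Aqp4 changed by 1.45 in wildtype and −0.61 in knockout, and Gja1 had an interaction of −1.84 ± 0.28. Fkbp5 and Zbtb16 fell after injury in wildtype, by 2.24 and 2.81, and changed by 1.34 and 0.01 in knockout. For cholesterol genes camera gave an adjusted p of 1e-12, and adjusted p = 0.5 with an estimated correlation; the homeostatic list (1 of 22 higher, 4 lower, median −0.31) was also called, with adjusted p = 0.5 by that correlation.

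Hmgcs1 and Fkbp5, which lay apart between the genotypes in uninjured cord, were closer at 7 dpi. The knockout and wildtype levels there were 26.7 ± 10.3 and 19.8 ± 7.22 CPM for Hmgcs1 and 37.4 ± 14.6 and 20.8 ± 6.78 CPM for Fkbp5. Without wildtype uninjured animal 3 the count for astrocytes was 178, without wildtype 7 dpi animals 1 and 2 it was 113 and 168, without uninjured knockout animals 1, 2 and 3 it was 189, 171 and 164, and without knockout 7 dpi animals 1, 2 and 3 it was 243, 204 and 668. Without the filter it was 671, without TMM factors the Astrocyte split was 120 higher and 276 lower, and within clusters 4 and 5 alone it was 109 and 176.

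How microglia and macrophages respond to injury in wildtype cord was asked in the same way. Genes of the lipid-laden, phagocytic state rose steeply in the class as a whole. The class pools microglia and macrophages, and cluster 13 went from 8.57% to 71.4% of it in wildtype. A change within cells and a replacement of cells were therefore not told apart. Gpnmb, a glycoprotein of lipid-rich phagocytes, went from 10.6 ± 7.43 to 2005 ± 458 CPM (198-fold; SD, n = 3), Apoe, a lipid carrier, from 76.8 ± 19.6 to 702 ± 37.4 CPM (8.93-fold), and Igf1 from 3 to 879 UMIs, a ratio of 65.7 (95% counting interval 22.4 to 319). Atp6v0d2, a subunit of the proton pump of lysosomes, had 0 UMIs in uninjured cord and 975 at 7 dpi, at least 72.8-fold higher against a floor of 3 UMIs over the group. Microglial identity genes fell, with Siglech going from 598 ± 111 to 120 ± 35.3 CPM (4.83-fold lower) and Selplg from 697 ± 78.0 to 127 ± 23.6 CPM (5.29-fold lower). The animals did not overlap for any of these genes.

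The list of disease-associated microglia rose in 20 of 21 (median 2.52, which setting Atp6v0d2 to its bound does not move; camera adjusted p = 2.9e-40), and phagocytosis and lipid genes in 18 of 22 with 2 lower (median 2.25, 2.2e-28), among them the cholesterol exporters Abca1 (2.63 ± 0.19) and Abcg1 (2.68 ± 0.22). Macrophage markers rose in 5 of 9 and fell in 2 (median 3.33), with Ms4a7 at 5.52 ± 0.40, Lyz2 at 3.33 ± 0.37 and Spp1 going from 2 to 660 UMIs, a ratio of 74.0 (20.4 to 612). These calls held with an estimated correlation, as did that of oligodendrocyte stress genes (6 of 11 higher, with Anxa2 at 3.24 ± 0.54 and Sgk1 at 1.10 ± 0.22), and the other 12 of the 15 camera calls outside the marker lists did not. Within cluster 16 alone Sgk1 in microglia and macrophages was at −0.227. Homeostatic microglia genes fell in 14 of 16 (15 adjusted over the list alone, median −1.49), with Selplg at −2.40 ± 0.17, Siglech at −2.27 ± 0.19, the transcription factor Sall1 at −2.34 ± 0.24 and Slc2a5 at −4.42 ± 0.54; camera gave an adjusted p of 3.3e-19, and adjusted p = 0.051 with an estimated correlation. Plexins and neuropilins changed in 8 of 10. Plxnc1 (3.95 ± 0.36), Plxna1 (3.12 ± 0.40), Plxnd1 (3.23 ± 0.59), Plxna2 (1.92 ± 0.42), Nrp1 (1.43 ± 0.19) and Nrp2 (1.49 ± 0.21) rose, while Plxna4 (−1.69 ± 0.20) and Plxnb3 (−1.34 ± 0.30; 0.0496 for Plxnb3 in microglia and macrophages of cluster 16 alone) fell, with adjusted p = 0.11 for the list by the estimated correlation. Of 11 Plexin-B signalling genes Arhgap5 (−1.62 ± 0.18), Pik3r1 (−1.08 ± 0.17) and Mras (−1.69 ± 0.32) fell (camera adjusted p = 0.034, and adjusted p = 0.36 with an estimated correlation). Oligodendrocyte markers were lower in 6 of 10 (9 adjusted over the list alone, median −1.13), including Mobp (−1.91 ± 0.23) and Mbp (−1.05 ± 0.21), with adjusted p = 0.26 by the estimated correlation.

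In all 1812 of 9600 genes changed, 944 higher and 868 lower, of which 1684 had no overlap, against 32.7% of all genes and 10% by chance. Several more of the steepest genes were at 0 UMIs in uninjured wildtype, so that Anpep was at least 32.7-fold, Fabp5 at least 18-fold, Thbs1 at least 12.8-fold and Rgs1 at least 9.19-fold higher. Other low changes were those of Zbtb16 (−4.02 ± 0.60), Crybb1 (−3.84 ± 0.39), Cacnb2 (−3.01 ± 0.20), Lifr (−2.95 ± 0.22) and Bank1 (−2.64 ± 0.30). Within cluster 16 alone, which held 90.1% of the class before and 26.5% after injury, 155 genes changed.

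Whether microglia and macrophages without Plexin-B1 respond alike was asked in the knockout. The lists of disease-associated microglia, phagocytosis and lipid genes and homeostatic microglia moved in the same direction as in wildtype. Camera called 12 lists outside the marker lists here and 15 in wildtype. Gpnmb went from 3 to 4524 UMIs, a ratio of 1313 (449 to 6371), Igf1 from 14.4 ± 3.43 to 371 ± 38.3 CPM (24.8-fold), Lgals3, which encodes galectin 3, by 4.68 ± 0.29 and Cd300lf from 4.11 ± 2.23 to 338 ± 33.6 CPM (79.6-fold). Siglech fell from 814 ± 69.1 to 103 ± 8.87 CPM (7.93-fold), Tmem119 from 149 ± 18 to 20.6 ± 2.72 CPM and Cst3, which encodes cystatin C, from 295 ± 28.8 to 22.3 ± 7.34 CPM (14.0-fold). Genes of disease-associated microglia rose in 18 of 21 and fell in 1 (median 2.45, camera adjusted p = 4.5e-33), phagocytosis and lipid genes rose in 17 of 22 and fell in 1 (median 1.80, 5.1e-20), and homeostatic microglia genes fell in 15 of 16 (median −1.74, 2e-19), with P2ry12 at −2.44 ± 0.20 and Cx3cr1 at −1.78 ± 0.16. Within cluster 13 alone Cx3cr1 in microglia and macrophages was at 0.0228. These calls, that of the macrophage markers (6 of 9 higher) and that of oligodendrocyte stress genes (7 of 11 higher) held with an estimated correlation, and 4 of 12 camera calls outside the marker lists did. Cholesterol synthesis genes fell in 10 of 13 (median −1.42), with Cyp51 at −2.17 ± 0.40 and Msmo1 at −1.83 ± 0.35, and adjusted p = 0.054 by the estimated correlation. Cyp51 and Cst3 were higher in uninjured knockout than in uninjured wildtype, so their fall also holds that difference. Plxnc1 (4.53 ± 0.26), Plxna1 (3.18 ± 0.27), Plxnd1 (3.54 ± 0.42) and Nrp2 (1.43 ± 0.17) were among 7 of 10 plexins and neuropilins that rose, and Sema5a (−1.04 ± 0.21) and Sema6a (−0.87 ± 0.28) fell. In nuclei with a doublet score under 0.1 the direction of these 2 semaphorins turned, and Sema5a turned within cluster 13 alone too (0.274), with Sema5a in microglia and macrophages at 0.22 and Sema6a in microglia and macrophages at 0.64.

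In all 3406 genes changed, 1882 higher and 1524 lower, 3229 of them without overlap (48.3% of all genes, 10% by chance). The responses again shared direction, since 94.9% of the 1812 genes called in wildtype moved the same way, 798 were higher in both (185 by chance), 592 lower in both (138 by chance) and 13 opposite, with r = 0.806 across 6063 abundant genes. Within cluster 13 alone 982 genes changed, within cluster 16 alone 1119, and in nuclei of 500 to 2000 UMIs 1753. In cluster 13 uninjured knockout animal 1 had 17 nuclei, under the minimum, and was left out. Median UMIs per nucleus of this class were 1912 in uninjured knockout and 787 in knockout cord at 7 dpi.

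**Figure D4:**
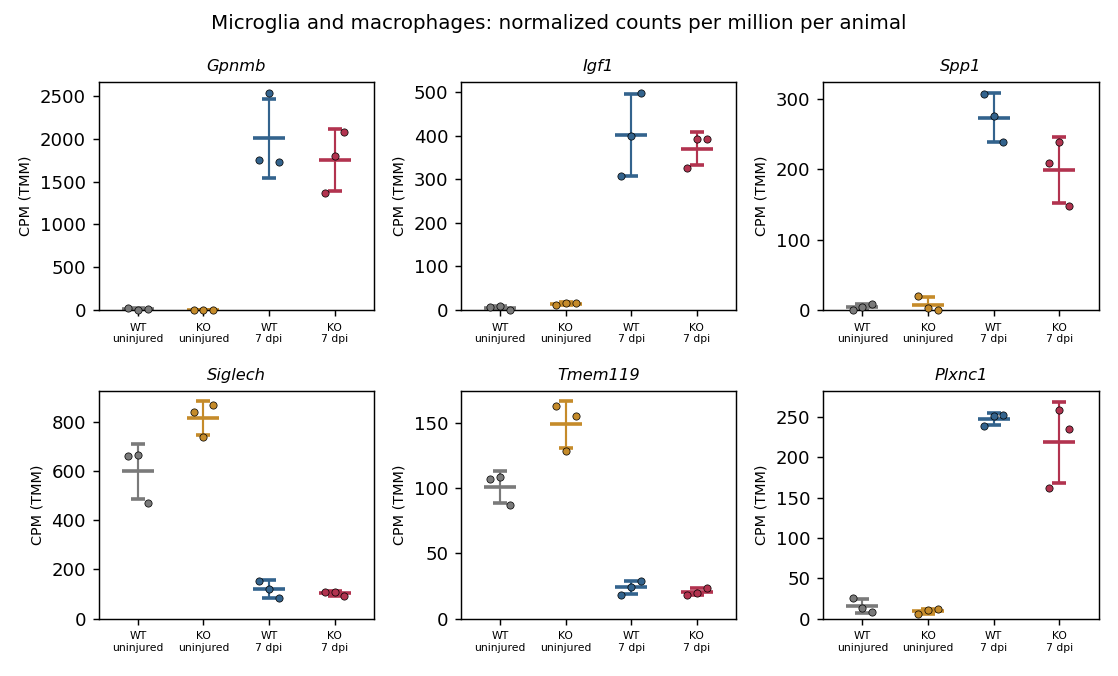
Levels of 6 genes of microglia and macrophages (CPM, vertical axis) by condition; points are animals, bars the mean and whiskers 1 SD (n = 3). Gpnmb rose from 10.6 to 2005 CPM in wildtype and from 1.33 to 1753 CPM in knockout, and Siglech fell from 598 to 120 CPM and from 814 to 103 CPM.

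In uninjured cord, where the question is what the loss of Plexin-B1 does to resting microglia, 183 genes differed, 67 higher and 116 lower in the knockout. The higher ones included Cst3 (295 ± 28.8 against 76.6 ± 54.7 CPM, 3.39-fold, adjusted p = 0.00014), the lysozyme gene Lyz2 (72.5 ± 8.53 against 17.2 ± 11.6 CPM, 3.67-fold, adjusted p = 0.018), Mpeg1 (1.57 ± 0.31), Cdh11 (1.81 ± 0.37), Sytl2 (1.61 ± 0.31) and Uchl5 (2.60 ± 0.61). The lower ones included Zbtb16 (−3.18 ± 0.55), the cyclin gene Ccnd3 (−2.11 ± 0.32), Crybb1 (−1.70 ± 0.31), Rn18s-rs5 (−2.22 ± 0.19) and the astrocyte glutamate transporter gene Slc1a3 (117 ± 11.5 against 341 ± 68.8 CPM). None of these overlapped between the 3 knockout and 3 wildtype animals. Of 13 cholesterol genes 2 were higher (4 adjusted over the list alone, median 1.09), among them Cyp51 with 83 against 2 UMIs (ratio 9.97, 2.68 to 83.7), with adjusted p = 0.22 by the estimated correlation. Markers of astrocytes were lower in 2 of 5 (median −1.24), Slc1a3 and Gpc5 (−1.24 ± 0.27), with adjusted p = 0.030 by the estimated correlation, and those of neurons in 1 of 5 (median −0.66, adjusted p = 0.32 by that correlation). Whether these marker changes came from RNA of other cells was not tested.

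Of the 183 genes 175 had no overlap (21.1% of all genes, 10% by chance), and the knockout nuclei held a median of 1912 UMIs against 833 in wildtype. In microglia and macrophages the count was 75, 92 and 303 without uninjured wildtype animals 1, 2 and 3 and 76, 99 and 74 without uninjured knockout animals 1, 2 and 3. Without TMM factors the IAMs split was 106 higher and 74 lower and without the filter 99 and 59, and in nuclei of at least 1000 UMIs 36 genes differed.

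At 7 dpi, where the question is whether Plexin-B1 shapes the microglia and macrophages of the lesion, 5 of 9600 genes differed, all higher in the knockout, all without overlap and all with an adjusted p of 0.045. Among them were Sytl2 (118 ± 17.9 against 57.1 ± 9.69 CPM, 2.13-fold), Jakmip3 (140 ± 20.3 against 66.3 ± 9.94, 2.08-fold), Anks1b (275 ± 39.2 against 137 ± 16.6, 2.00-fold) and Lhfpl3 (177 ± 15.9 against 89.4 ± 16.9, 1.98-fold). These genes stood higher in neural cells, with Lhfpl3 at 4255 CPM in OPCs and Sytl2 at 930 CPM in oligodendrocytes of the same knockout animals. Oligodendrocyte and myelin markers (medians 0.79 and 0.79, with Mbp at 0.80 ± 0.20, not past the test) and those of OPCs (0.79) and neurons (0.60) were called higher by camera. With an estimated correlation adjusted p = 0.059, adjusted p = 0.19, adjusted p = 0.037 and adjusted p = 0.065 for these 4 lists. Genes of disease-associated microglia (median −0.20), phagocytosis and lipid genes (−0.14) and plexins (−0.29) were called lower, with no member past the test, Gpnmb at −0.20 ± 0.17, Apoe at −0.03 ± 0.16 and Plxnb1 at −0.40 ± 0.53. With the estimated correlation adjusted p = 0.19, adjusted p = 0.25 and adjusted p = 0.25, and none of the 10 calls outside the marker lists held.

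Unadjusted p was below 0.05 for 567 genes, 12.8% of genes had no overlap where chance gives 10%, and 43.3% of simulated 2-fold changes were found. The count for microglia and macrophages was 0 with DESeq2, without TMM factors, with the replicate block, with sex as a covariate, in nuclei with a doublet score under 0.1, without clusters led by other markers, without wildtype 7 dpi animals 1 or 2, uninjured knockout animal 3 or knockout 7 dpi animal 2, and 1 without knockout 7 dpi animal 1. It was 9, 12 and 67 without uninjured wildtype animals 1, 2 and 3, 8 without wildtype 7 dpi animal 3, 9 without uninjured knockout animal 2 and 13 without knockout 7 dpi animal 3, 46 without the filter on low counts and 63 with only the 2 groups compared in the fit.

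The interaction of injury and genotype was passed by 44 genes of microglia and macrophages, 37 with a higher and 7 with a lower response in the knockout. Here too the uninjured difference enters the interaction. Lyz2 and Mpeg1 were higher in uninjured knockout, and Slc1a3, Gpc5 and Rn18s-rs5 were lower there. Plxnb1 was at 1.73 ± 0.85 (adjusted p = 0.41). Lyz2 rose by 3.33 in wildtype and 1.14 in knockout, Mpeg1 changed by 1.59 and −0.33, and Olfml3 by −0.20 and −2.26. Slc1a3 changed by −2.07 in wildtype and −0.07 in knockout, Gpc5 by −0.88 and 1.00, Cdh13 by −0.92 and 1.27, Meg3 by −0.50 and 1.46 and Rn18s-rs5 by 0.06 and 2.15. Astrocyte markers had a median interaction of 1.87 (2 of 5 called), a call that held with an estimated correlation (adjusted p = 0.019), and neuron markers one of 1.38 (1 of 5 called, adjusted p = 0.056 with that correlation). Slc1a3 and Gpc5 are astrocyte markers and Meg3 is a neuron marker. Their interaction therefore cannot be assigned to microglia and macrophages alone, and RNA from other cells was not tested as its source. In microglia and macrophages the count was 11, 24 and 27 without wildtype 7 dpi animals 1, 2 and 3, 26 and 16 without uninjured knockout animals 1 and 3, and 27 and 106 without knockout 7 dpi animals 2 and 3. DESeq2 called 72 genes, and 14 were called within cluster 16 alone.

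**Figure D5:**
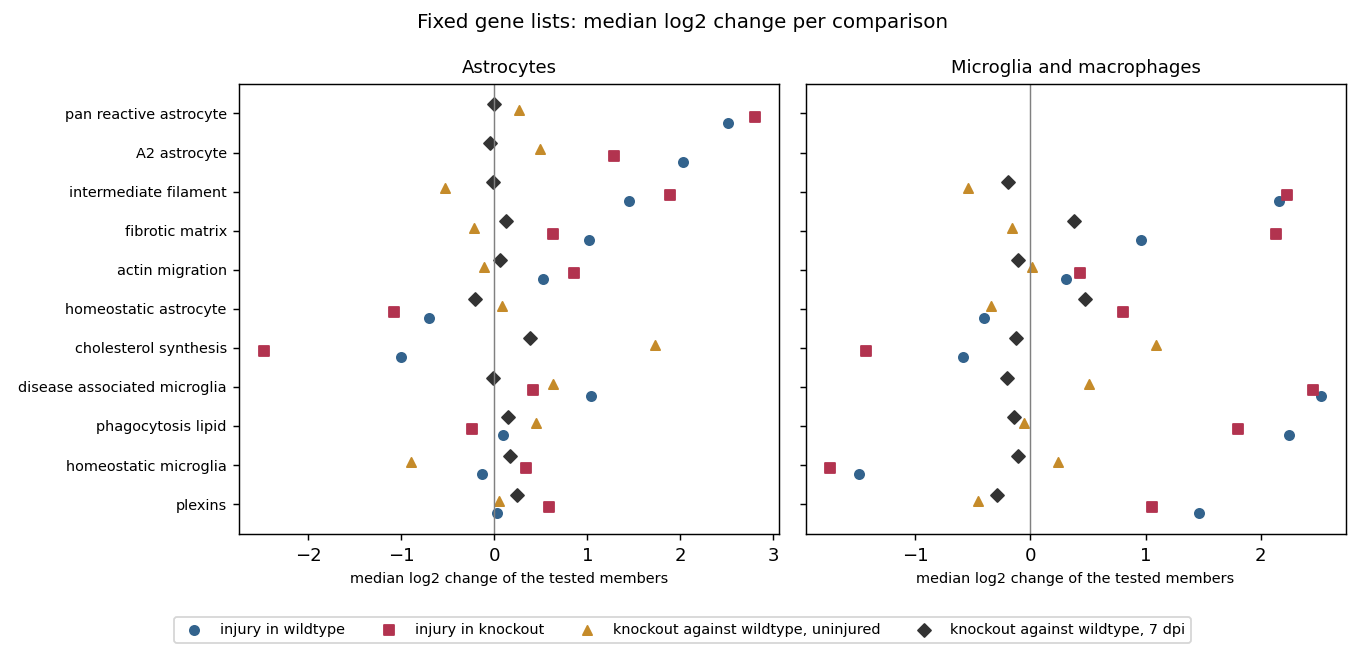
Median log2 change of the tested members (horizontal axis) of gene lists fixed in advance (vertical axis) in 4 comparisons, for astrocytes and for microglia and macrophages; lists with fewer than 5 tested members have no point. In astrocytes pan-reactive genes lie at 2.52 and 2.80 after injury and cholesterol genes at 1.73 between uninjured knockout and wildtype.

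The other cell types were compared in the same 5 ways. Their counts do not measure how far a response reached, since power differed between types. For injury in wildtype 55.2% of simulated 2-fold changes were found in neurons, 26.9% in ependymal and 17.9% in endothelial cells. After injury in wildtype 1853 genes changed in OPCs, 1281 in neurons, 1172 in oligodendrocytes, 481 in fibroblasts, 14 in endothelial cells and 0 in ependymal cells (edgeR; 498 with an unadjusted p below 0.05). Oligodendrocytes raised the complement gene C4b (2.99 ± 0.33) and Megf6 (2.86 ± 0.21) and lowered Zbtb16 (−2.91 ± 0.38) and Htra1 (−2.36 ± 0.54). OPCs raised the mechanosensitive channel gene Piezo2 (3.97 ± 0.44) and Col20a1 (3.97 ± 0.25), neurons the injury-induced peptidase gene Ecel1 (2.45 ± 0.26), and fibroblasts Col7a1 (3.84 ± 0.46) and Kif26b (3.24 ± 0.31). Dkk2, a Wnt antagonist, went from 0 to 193 UMIs in fibroblasts, at least 36.6-fold. In the knockout 11158 genes changed in neurons, 4848 in oligodendrocytes, 3783 in OPCs, 2150 in fibroblasts, 233 in endothelial and 230 in ependymal cells. Uninjured knockout neurons held a mean of 11775 UMIs per nucleus against 4940 in uninjured wildtype, so the counts of the 2 genotypes do not rest on equal depth. C4b rose by 4.94 ± 0.35 in oligodendrocytes and 4.65 in OPCs, Ecel1 by 3.27 in neurons and the matrix gene Postn by 3.66 in fibroblasts. Serinc1 fell in neurons by 2.32, in oligodendrocytes by 2.57 and in OPCs by 3.00, and Hmgcs1 in oligodendrocytes by 2.76. In oligodendrocytes both genes, and in neurons Serinc1, were already higher in uninjured knockout than in uninjured wildtype.

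Between uninjured knockout and wildtype 7447 genes differed in neurons, 3798 in oligodendrocytes, 881 in OPCs, 243 in fibroblasts, 159 in endothelial cells and 11 in ependymal cells. Cyp51 (1.97 ± 0.16) and Hmgcs1 (1.90 ± 0.15) were higher in oligodendrocytes and Msmo1 (1.90) in OPCs, all of cholesterol synthesis. Serinc1 was higher in neurons (1.91), oligodendrocytes (1.89) and fibroblasts (2.17). Zbtb16 was lower in oligodendrocytes (−3.36 ± 0.37), OPCs (−3.31) and fibroblasts (−2.46), and Erdr1y was lower in oligodendrocytes (−3.22), OPCs (−2.79), neurons (−3.06), fibroblasts (−2.80), endothelial cells (−3.06) and ependymal cells (−2.85). The guidance receptor gene Nrp1 was higher in fibroblasts (1.10 ± 0.24) and neurons (0.33 ± 0.09). Median UMIs per nucleus were 2198 against 1071 in oligodendrocytes and 2299.5 against 1486 in neurons, and a single cluster, number 8, held 34.4% of uninjured knockout and 7.42% of uninjured wildtype oligodendrocytes.

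At 7 dpi knockout and wildtype differed by 1 gene in oligodendrocytes and by 0 in OPCs, neurons, fibroblasts, endothelial, ependymal and dividing cells. The 1 gene, which falls outside the rule for named genes and is named after its values were seen, was Esyt3, a tether of the endoplasmic reticulum to the plasma membrane, at 36.3 ± 5.63 against 10.1 ± 2.85 CPM (1.83 ± 0.29, adjusted p = 0.010, no overlap). In the types at 0 edgeR gave unadjusted p below 0.05 for 308, 786, 444, 118, 110 and 432 genes in that order, and DESeq2 called 0, 1, 19, 0, 0 and 0. Of simulated 2-fold changes at 7 dpi 52.2% were found in neurons, 14.9% in endothelial and 8.96% in ependymal cells. Plxnb1 itself missed the threshold at 7 dpi in oligodendrocytes (−1.07 ± 0.19, adjusted p = 0.052), OPCs (−1.15 ± 0.24, 0.39) and fibroblasts (−1.49 ± 0.33, 0.25). The interaction was passed by 2697 genes in neurons, 1096 in oligodendrocytes, 77 in endothelial cells, 74 in OPCs, 11 in fibroblasts and 0 in ependymal cells (251 with an unadjusted p below 0.05), together 3955, and 1964 to 6192 with 1 animal left out. In oligodendrocytes Zbtb16 (3.58) and Camk1d (3.64) had a higher and Cyp51 (−2.33) and Hmgcs1 (−2.29) a lower response in the knockout.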

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

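Of the tests given here, those of nuclei of like depth, of the correlation between types in other splits, of Plxnb1 acting alike in uninjured and injured cord and of the neighbours of Plxnb1 were chosen after the results they measure were seen. Injury responses that differed between the genotypes by the interaction test, which also holds differences present in uninjured cord alone, are the results listed. They numbered 369 genes in astrocytes, 44 in microglia and macrophages, 1096 in oligodendrocytes, 74 in OPCs, 2697 in neurons, 11 in fibroblasts and 77 in endothelial cells. In astrocytes the knockout response was higher for Fkbp5 (3.58), Erdr1y (3.06), Zbtb16 (2.82), Nrros (2.00), Ptprj (2.00), Rn18s-rs5 (1.92), Hif3a (1.91), Plcl2 (1.88), Lrrc8c (1.85) and Pabpn1 (1.84) on the log2 scale. It was lower for Hsd17b7 (−2.66), Serinc1 (−2.25), Tmem47 (−2.20), Acvr1c (−2.20), Gpr37l1 (−2.14), Prnp (−2.14), Aqp4 (−2.06), Col12a1 (−1.96) and Cyp51 (−1.89). In microglia and macrophages it was higher for Cdh13 (2.19), Rn18s-rs5 (2.09), Ryr2 (2.05), Grik4 (2.02), Slc1a3 (1.99), Hdgfl2 (1.98), Meg3 (1.97), Jdp2 (1.91), Rcan2 (1.88) and Gpc5 (1.87), and lower for Lyz2 (−2.20), Olfml3 (−2.06), Mpeg1 (−1.92), Adamts16 (−1.77), Psd3 (−1.29) and Arsb (−1.10). Slc1a3, Gpc5 and Meg3 are markers of astrocytes or neurons, and RNA from those cells was not tested as the source of their interaction.

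The differences between uninjured knockout and wildtype cord correlated between the 8 cell types compared by a median of 0.633 over 28 pairs (lowest 0.378), against 0.117 at 7 dpi, but the types come from the same animals: from log CPM the genotypes gave 0.629, the 9 other splits of the 6 animals 0.289 to 0.445, and 1 animal against the 2 others of its genotype 0.155 to 0.357. At 7 dpi the genotypes gave 0.109, below the other splits (0.175 to 0.348) and 1 animal against the 2 others of its genotype (0.176 to 0.424). More UMIs per nucleus in the knockout, taken as the count itself, is argued against in astrocytes, OPCs, oligodendrocytes and fibroblasts. This does not cover a difference in preparation that goes with depth, which was not tested. In these types all called genes, those below the count filter included, had 91.3%, 105%, 88.4% and 98.0% of their median change in nuclei of 500 to 2000 UMIs. Those nuclei were no deeper in knockout than in wildtype (819 against 1164, 882 against 1089, 927 against 1022 and 915 against 1012 UMIs per nucleus). They were shallower rather than matched in the first 2, and the limit on depth was made one-sided after these values were seen. Many calls ended there (823 of 1802, 372 of 881, 1738 of 3798 and 129 of 243 were left): these nuclei held 20.7%, 19.0%, 23.6% and 25.1% of the UMIs, and in the genes tested again the median change went from 0.799 to 0.757, 0.877 to 0.935, 0.663 to 0.594 and 1.04 to 1.01 and the median standard error from 0.195 to 0.253, 0.214 to 0.314, 0.162 to 0.212 and 0.231 to 0.281. Depth stays open elsewhere, with 71.5% in neurons, 63.8% in endothelial cells, 11 genes alone in ependymal cells (98.9%) and deeper knockout nuclei in microglia and macrophages (86.6%, 1178 against 869 UMIs), and a correlation of 0.120 with the change from shallow to deep wildtype astrocytes says nothing, as that change correlated between animals by 0.0927 at most, whereas loss of Plxnb1 acting alike before and after injury is argued against in astrocytes by a correlation of −0.041 between the uninjured and 7 dpi changes of 1801 called genes, of which 882 had the same sign. Lower glucocorticoid signalling in the uninjured knockout mice at collection, or higher in the uninjured wildtype mice, may account for part of the pattern. Of the 12 glucocorticoid-induced genes not looked at before, 10 lay below 0 in astrocytes, 1 of them called, and 2 above, with Pdk4 called at 1.33. Their median was −0.489, at percentile 0.2 of 10000 random lists, and it was below 0 in 8 of 8 types, in neurons at percentile 41. Genes of 1 list and types of the same animals are not independent, so the percentile and the 8 types are weak support. In astrocytes Fkbp5 stood at 92.4 CPM in uninjured wildtype, 14.8 in uninjured knockout, and 20.8 and 37.4 in wildtype and knockout at 7 dpi. Zbtb16 and Hif3a changed after injury by −2.81 and −1.81 in wildtype and by 0.01 and 0.10 in knockout. Which uninjured group moved stays open. More cytoplasmic RNA carried with the nuclei stays open too. The median of ribosomal protein genes in astrocytes, −0.119 (bootstrap 95% interval −0.35 to 0.03), lay below the 0.3 it needs but not clearly below 0. The 7 nuclear-retained RNAs were lower, as it needs (median −0.48), while 4 mitochondrial genes were too (−0.69). An effect of Plxnb1 in intact cord alone, free RNA shared by the types of an animal and a difference in housing or handling were not tested.

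Slc38a3, lower in knockout astrocytes at 7 dpi, lies near Plxnb1, and DNA flanking the deletion from the strain in which it was made is a candidate explanation. Of the 100 tested neighbours of Plxnb1, 6 had an unadjusted p below 0.05 in the same direction in both genotype contrasts, against a median of 0 and at most 4 in 195 windows of the same size elsewhere, as this explanation needs; without Slc38a3, which prompted the test, 5 of 99 did. Among them were Mapkapk3 (−1.20 uninjured, −0.70 at 7 dpi), Cacna2d2 (−1.28, −0.88), Slc38a3 (−0.52, −1.03), Als2cl (−0.93, −0.56) and Gadl1 (1.22, 0.59). An effect of Plexin-B1 itself on Slc38a3 stays open and was not tested, and Dao was not part of this test.

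The neural genes higher in knockout microglia and macrophages at 7 dpi could come from free RNA of other cells or from doublets, and neither test decided. For free RNA the 5 genes had a median of 0.523 in fibroblasts and 0.294 in endothelial cells, against 1.00 in the class itself. For doublets the median was 0.798 in nuclei with a doublet score under 0.1, where 0 of the 5 genes were still called on 71.2% of the UMIs of the class. Uptake of neural debris by the cells, the biological alternative, was not tested.

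With 3 animals against 3 there are 10 splits, too few for a share under 0.05, so only the real count and the highest other are given; the real split was the only 1 of the 10 with as many genes unless its count was 0, where all 10 had as many. In astrocytes the counts were 2241 against 0 for injury in wildtype, 5476 against 0 in knockout, 1802 against 0 uninjured and 3 against 0 at 7 dpi, and in microglia and macrophages 1812 against 0, 3406 against 0, 183 against 0 and 5 against 1. In the same order they were 1172 against 0, 4848 against 1, 3798 against 0 and 1 against 0 in oligodendrocytes, 1853 against 0, 3783 against 0, 881 against 0 and 0 against 1 in OPCs, and 1281 against 0, 11158 against 0, 7447 against 0 and 0 against 19 in neurons. They were 481 against 0, 2150 against 0, 243 against 3 and 0 against 0 in fibroblasts, 14 against 0, 233 against 25, 159 against 0 and 0 against 0 in endothelial cells, and 0 against 0, 230 against 0, 11 against 0 and 0 against 0 in ependymal cells, and 0 against 0 at 7 dpi in the dividing class. For the interaction 60 regroupings of the animals were used, the real one included, extended from 30 after the counts of those were seen. The count does not exclude chance for astrocytes (369 genes; 6 of 60 gave as many, highest other 975), microglia and macrophages (44; 4 of 60, 77), oligodendrocytes (1096; 5 of 60, 1922), OPCs (74; 8 of 60, 684), neurons (2697; 5 of 60, 5135), endothelial cells (77; 3 of 60, 98), fibroblasts (11; 10 of 60, 93) or ependymal cells (0; 60 of 60, 13). In the first 6 of these the other regroupings that reached the real count are among 7 that keep the uninjured animals grouped by genotype and so retain the uninjured difference, a structure of the samples, and the count decides little. With the uninjured animals mixed the highest counts were 2, 36, 0, 3, 0 and 16 in these 6 types, and 52 in fibroblasts, above the 11 of the real grouping.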

How the results depend on the processing

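The 7 alternatives with nuclei of 500 to 2000 UMIs (for genes and for shares), a doublet score under 0.1, sex as a covariate, no uninjured knockout animals, no clusters led by markers of another class, or nuclei of 1 cluster were chosen after the data were seen, and the other 18 before. The cause of the changes listed was not tested, except that thinning, single clusters and narrower sets of nuclei hold fewer UMIs by construction, and a limit on the size of change can only lower a count. Counts not given here stayed within 1.5 times the reported ones.

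With the summed counts thinned to the lowest total, astrocytes had 1472, 2723, 742 and 117 changed genes for injury in wildtype, injury in knockout, uninjured genotypes and the interaction (2241, 5476, 1802 and 369 as reported), microglia and macrophages had 927, 1008, 69, 0 and 19 for these 3, then 7 dpi, then the interaction (1812, 3406, 183, 5 and 44), and the 6 other types together had 2578, 10832, 5428, 0 and 1744 (4801, 22402, 12539, 1 and 3955). In nuclei of 500 to 2000 UMIs astrocytes had 1442, 3446, 1155 and 236, microglia and macrophages 1191, 1753, 76, 0 and 16, and the 6 other types 2293, 10009, 5541 and, for the interaction, 1304. With a log2 change of at least 1 either way astrocytes had 1187, 2564 and 635, microglia and macrophages 1952 in knockout, 104 uninjured and 3 at 7 dpi, and the 6 other types 2304, 8973, 2649 and, for the interaction, 1556. Within cluster 4 astrocytes had 908, 2617, 1165, 1 and 109, and within cluster 5 790, 3627, 583 and, for the interaction, 176. Microglia and macrophages within cluster 13 had 982 for injury in knockout and 18 at 7 dpi, and within cluster 16 155, 1119, 0 at 7 dpi and 14 for the interaction. Without a filter on low counts astrocytes had 15 at 7 dpi and 671 for the interaction, microglia and macrophages 46 at 7 dpi and the 6 other types 73 at 7 dpi.

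The 5 genes of microglia and macrophages at 7 dpi became 0 with DESeq2, 0 with library size only, 0 with the replicate block, 0 with a doublet score under 0.1, 0 with sex as a covariate, 0 without the 3 uninjured knockout animals, 0 without clusters led by other markers, 3 in nuclei of at least 1000 UMIs and 63 with only the 2 groups compared in the fit. Their uninjured count became 104 with only the 2 groups and 36 in nuclei of at least 1000 UMIs, and the interaction 72 with DESeq2. The 6 other types at 7 dpi had 21 with DESeq2, 4 with only the 2 groups, 0 in nuclei of at least 1000 UMIs, 2 with a doublet score under 0.1 and 4 without the 3 uninjured knockout animals, and 2563 for the interaction with a doublet score under 0.1. Of the shares, 4 types were called after injury in wildtype in nuclei of 500 to 2000 UMIs, 4 after injury in knockout without neurons, and 2 (microglia and macrophages, endothelial cells) both in uninjured cord and for the interaction in nuclei of at least 1000 UMIs. In these 2 types that limit kept a larger part of the nuclei in uninjured knockout than in uninjured wildtype. Plxnb1 moved with TMM factors to 112 CPM in uninjured wildtype oligodendrocytes and to 136 and 58.9 CPM in uninjured wildtype and knockout ependymal cells.

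Called lists in astrocytes went from 19, 15, 6, 3 and 9 (injury in wildtype, injury in knockout, uninjured, 7 dpi, interaction) to 5, 2, 0, 0 and 0 with an estimated correlation. In fry, which tests a list on its own, 29, 10, 0 and 1 were called from the second on, and with abundant members alone 9 in knockout and 5 for the interaction. In microglia and macrophages they went from 15, 12, 4, 10 and 6 to 3, 4, 0, 0 and 0 with an estimated correlation and to 23, 23, 2, 0 and 0 in fry.

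Leaving out 1 animal at a time gave, in that order of comparisons, 1508 to 2486, 4544 to 5775, 936 to 2112, 0 to 3 and 113 to 668 genes in astrocytes, 1334 to 1842, 2625 to 3874, 74 to 303, 0 to 67 and 11 to 106 in microglia and macrophages, and 2808 to 6059, 17384 to 23708, 8499 to 14219, 0 to 9 and 1964 to 6192 in the 6 other types. Called shares ranged from 6 to 8 types after injury in wildtype, from 4 to 7 in knockout (4 without uninjured knockout animal 3), and stayed at 0 in the other contrasts.

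Named genes past the threshold kept direction and call in 371 of 384 cases with DESeq2, 379 of 394 with the replicate block, 345 of 386 in nuclei of at least 1000 UMIs, 299 of 354 after thinning, 316 of 378 in nuclei of 500 to 2000 UMIs, 341 of 378 with a doublet score under 0.1, 4237 of 4656 with 1 animal left out, and, in single clusters, 106 of 131 in cluster 4, 99 of 145 in cluster 5, 19 of 30 in cluster 13 and 42 of 75 in cluster 16. The totals leave out genes that had no test under a setting, so a gene lost to the count filter was not counted as lost. Single genes reversed within a cluster or a set of nuclei chosen after the data were seen, and the cause was not tested. In cluster 5 Gpc5 had 1.00 in wildtype and 0.81 in knockout after injury, Slc7a10 1.06 and 1.09, Sema4b 0.435 and 0.525, Sema6d −0.0854 in wildtype, Sema3a −0.289 and Slco1c1 0.154 in knockout. In cluster 4 Sema6a had −0.0678 in wildtype. In microglia and macrophages of cluster 13 Cx3cr1 had 0.0228 and Sema5a 0.274 in knockout, and in cluster 16 Plxnb3 had 0.0496 and Sgk1 −0.227 in wildtype. With a doublet score under 0.1 Sema5a had 0.218 and Sema6a 0.640 in knockout microglia and macrophages, and Snap25 had 0.120 between uninjured astrocytes in nuclei of 500 to 2000 UMIs.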

Other observations

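The values in this part were chosen after the results were seen, from the planned tests unless stated. In injured ependymal cells the list of proliferation genes rose in 5 of 8 tested members in knockout (median 3.75, camera adjusted p = 8e-10, and adjusted p = 0.099 with an estimated correlation) and had a median of 2.63 with 0 of 8 called in wildtype. In the knockout Mki67 went from 1 to 42 UMIs, a ratio of 204 (95% counting interval 34.6 to 8228), and Top2a rose by 5.04 ± 0.87 on the log2 scale, while Prlr went from 134 to 2 UMIs. Of all ependymal nuclei 17 lay in the dividing cluster 28. The class deposited as Div-Myeloid, which is mixed by its markers, changed in 862 genes after injury in the knockout, 496 higher and 366 lower, with 3 animals against 2. Its OPC markers fell in 7 of 10 and rose in 1, and its macrophage markers rose in 5 of 7; whether its make-up changed was not tested. In it Itgbl1, Lilrb4b and Cd300lf were at 0 UMIs before injury and at least 13.7-fold, 10.0-fold and 9.48-fold higher at 7 dpi, and Bank1 fell by 3.90. In injured wildtype pericytes, with 2 animals against 2, the 2 changed genes were Zbtb16, from 36 to 2 UMIs, and Grm3, which fell by 2.25.

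Cluster 18, with Gpr17 among its leading genes, held 19.8% of wildtype and 26.9% of knockout OPCs in uninjured cord and 58.9% and 60.9% at 7 dpi. Zbtb16 fell after injury in wildtype in astrocytes (−2.81), microglia and macrophages (−4.02), oligodendrocytes (−2.91), OPCs (−4.70), fibroblasts (−3.41) and neurons (−1.18). In knockout astrocytes it changed by 0.01 after injury. Before injury it was already lower in knockout than in wildtype in astrocytes, microglia and macrophages, oligodendrocytes, OPCs and fibroblasts.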
